A study of Nicotiana tabacum with 30 samples.

How the data were processed

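RNA of tobacco leaves was sequenced in 30 libraries, 3 for each of the 10 combinations of 2 genotypes (K326 and M28) and 5 times (0, 1, 2, 4 and 8 h). Groups, times and replicate numbers were taken from the sample labels. The labels name leaf as the tissue, although their source field speaks of seeds. Nothing in the labels ties each library to separate plants beyond the pots described in the growth protocol, so p-values measure the spread between these samples, part of which may be technical.

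The authors deposited one table of FPKM values (fragments per kilobase of gene, relative to the mapped fragments of the library) with one column per library, and replicates were not pooled. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2 and featureCounts were used, with versions, roles and settings not given in the sources used here. The genome build and the step that made FPKM are also not given in the sources used here. The unit was taken from the name the authors gave the table and from its values, whose column totals differ between libraries. TPM computed over a larger set of genes could not be ruled out from the values alone, and in that case the steps between low values would compare sums of length-scaled reads and not reads. Gene IDs carry a scaffold field and a gene number, and 0 of 35519 IDs were found in the RefSeq table of the assembly ASM71507v2. The table does not pair IDs with names or descriptions. The 38 gene lists fixed before the data were examined therefore could not be matched and were not tested, and genes are given by ID, with at most 2 IDs per direction in each main comparison.

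FPKM values were analysed as log2(FPKM + 1), with a pseudocount of 1 FPKM, for the 19599 genes with a mean of at least 1 FPKM over the 30 libraries. Fold changes are on this scale, which understates the changes of low genes. Values were used as deposited with no further scaling. All 30 libraries entered one fit of the 10 groups with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and p-values were adjusted by the Benjamini-Hochberg method within each of 21 comparisons. A gene was called at an adjusted p below 0.05. The comparisons were each time against 0 h in each genotype, M28 against K326 at each time and over all times, and the difference between the genotypes' responses. The time courses and the interaction were tested with a moderated F test over 4 contrasts. Named genes were those with an adjusted p below 0.05, a log2 fold change of at least 1 in size, a mean of at least 5 FPKM in the higher group and no overlap between the libraries compared, ranked by the size of the change. The rule called for a description of each gene, which could not be had, so the first 2 IDs in each direction were taken. The design, the rule and the alternatives were fixed before the data were examined, apart from those named as added.

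The share of FPKM in the 100 most abundant genes, the FPKM total and the number of genes at 1 FPKM or more were compared between genotypes by an exact permutation test that exchanged libraries within times. Overlaps of gene calls were set beside the number that independent lists of the same sizes would share. All calls of a gene used the same residual spread from the fit of all libraries. This by itself can raise an overlap above that number, also where the fold changes share no library. Correlations across genes describe similarity of responses, and their error is a jackknife over libraries.

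Low values were examined for depth. For 2582 genes above 0 in few libraries, ratios between libraries were compared with ratios of whole reads from 1 to 3, within 0.002 on the log2 scale. Of these ratios 12.8% fell on a whole-read ratio at the best offset, against 0.2% at other offsets, and 92.2% of 435 library pairs fitted one set of relative depths within 0.005. Relative depth averaged 1.042 (SD 0.09) in K326 and 0.978 (SD 0.154) in M28, with 0.488 in M28 8 h replicate 3, so low genes are measured with less precision in that library. The absolute depth is unknown, and no counting interval was computed. Of 6526 genes with a median above 20 FPKM, 5 were listed at 0 in at least 1 library. Whether such an exact 0 is a failed estimate or a true absence was not tested. M28 8 h replicate 3 had 9 genes at 0 whose other replicates were both at 5 FPKM or more, against at most 3 in any other library.

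The fit was tested on simulated data with 200 changed genes among 19599. Changed genes were drawn only from those with a mean log2 value above that of 5 FPKM. Noise was normal and independent between genes. Each setting had 1 simulation, so the shares of false calls below rest on 5 to 16 false calls. Far more genes were called in the real data, so these rates may not hold for lower genes or for the real counts. Of genes changed 2-fold, 94.5% were recovered in the comparison of K326 8 h with 0 h, 94% in the K326 time course, 89% in the interaction and 99.5% in the genotype difference over all times. Of genes changed 1.5-fold, the shares were 66, 74, 30.5 and 99%, so small differences between responses were often not detectable. The share of false calls with genes changed 1.5-, 2- and 4-fold was 10.3, 6.32 and 6.19% in the interaction, 6.33, 4.57 and 7.41% in the K326 time course, 4.35, 2.58 and 5.21% in the comparison of K326 8 h with 0 h and 2.46, 5.24 and 2.44% in the genotype difference over all times, against the 5% aimed at. Alternatives tried were a pseudocount of 0.1 FPKM, no filter on low values, a mean of at least 5 FPKM, rescaling to equal totals, median-of-ratios scaling, quantile normalization, the replicate number as a block, a fit of only the groups compared, robust moderation, and each library left out in turn. The depth estimate and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.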

Results

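Leaf transcriptomes of tobacco (Nicotiana tabacum) were followed over a short drought series in the cultivar K326 and in M28, a line obtained from K326 by chemical mutagenesis with ethyl methanesulfonate and described by the submitters as more drought tolerant. Leaves were taken at 0, 1, 2, 4 and 8 h, with 3 libraries per genotype and time, giving 10 groups and 30 libraries. The protocol describes natural drought and simulated drought with 200 mM mannitol, and the sample labels do not say which of these each library had. No untreated library later than 0 h was used here, so the time under drought and the time of day changed together. Expression was given as FPKM for 35519 gene IDs, of which 8832 were listed at 0 in every library and 19599 had a mean of at least 1 FPKM and were tested. Totals of FPKM per library ran from 753424 to 855427. The depth in reads was not given, but the steps between low values placed the relative depth of M28 8 h replicate 3 at 0.488 and that of the other libraries between 0.905 and 1.274.

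The libraries separated by time and by genotype. The first principal component held 37.8% of the variance and ordered the K326 groups from a mean score of -59.59 at 0 h to 54.51 at 8 h, and the M28 groups from -32.37 to 69.48. The second component held 22.9% and separated the genotypes at each time. Pearson correlations between replicates of log2 values lay between 0.969 and 0.989, with the lowest in M28 at 8 h.

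**Figure D1:**
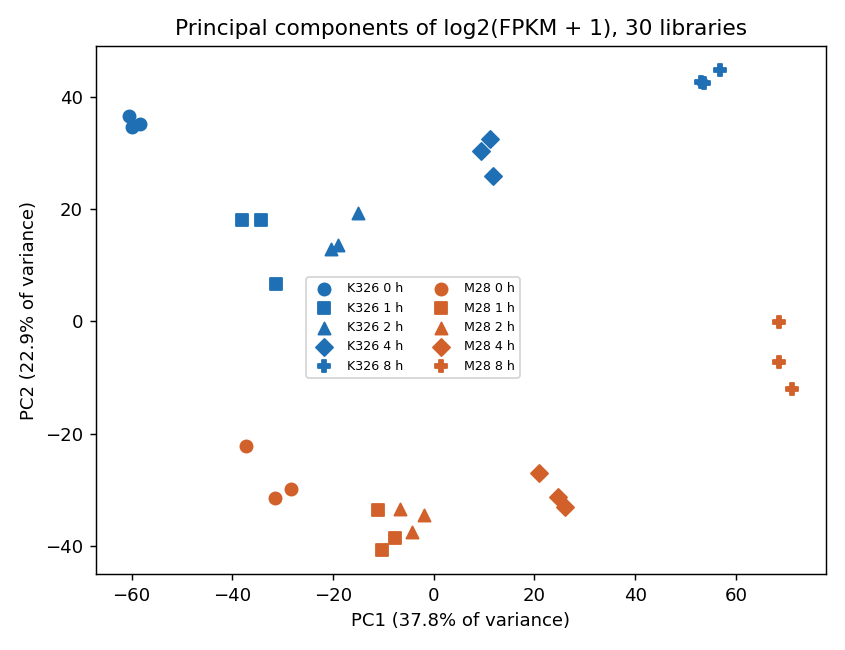
Scores of the 30 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance of each component in percent on its axis, color for genotype and marker shape for time. PC1 rises with time in both genotypes, and the M28 libraries at 0 h (mean -32.37) lie to the right of the K326 libraries at 0 h (mean -59.59).

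A small set of abundant genes held a smaller share of expression in M28 and at 8 h. The 100 genes with the highest mean FPKM held 36.25% ± 2.25 (SD, n = 3) of the FPKM total in K326 at 0 h and 26.77% ± 0.335 at 8 h. In M28 they held 27.76% ± 2.7 at 0 h and 19.64% ± 0.367 at 8 h. Averaged over the 5 times the share was lower in M28 (M28 minus K326, -7.43 percentage points), with no overlap between the genotypes at 5 of 5 times (two-sided exact permutation test within times over 3200000 rearrangements, p = 6.25e-07, the smallest this test can give). Of these 100 genes, 71 were lower and 11 higher in M28 than in K326 at 0 h, with a median log2 difference of -0.47. In K326, 60 of them fell and 27 rose from 0 to 8 h. In M28, 58 fell and 22 rose. The list of 100 genes was fixed on the mean of all 30 libraries, so the fall at 8 h is that of this list. The 10 most abundant genes of each library itself held 11.88 to 13.79% in K326 at 0 h and 12.17 to 12.61% at 8 h. In M28 they held 9.428 to 10.92% at 0 h and 7.891 to 8.362% at 8 h. The number of genes at 1 FPKM or more was higher in M28 by 416 (19520 against 19110 genes, the same exact permutation test, p = 1.25e-06), without overlap at 4 of 5 times. The share of the 100 genes and this number were 2 of 3 such measures tested. The other was the FPKM total, which was 782400 in M28 and 831800 in K326 (exact permutation p = 6.25e-07). The 3 measures come from the same values and are not independent. A smaller share in abundant genes can by itself bring more of the other genes to a fixed 1 FPKM. The number of genes at that level was not recounted under other scaling.

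**Figure D2:**
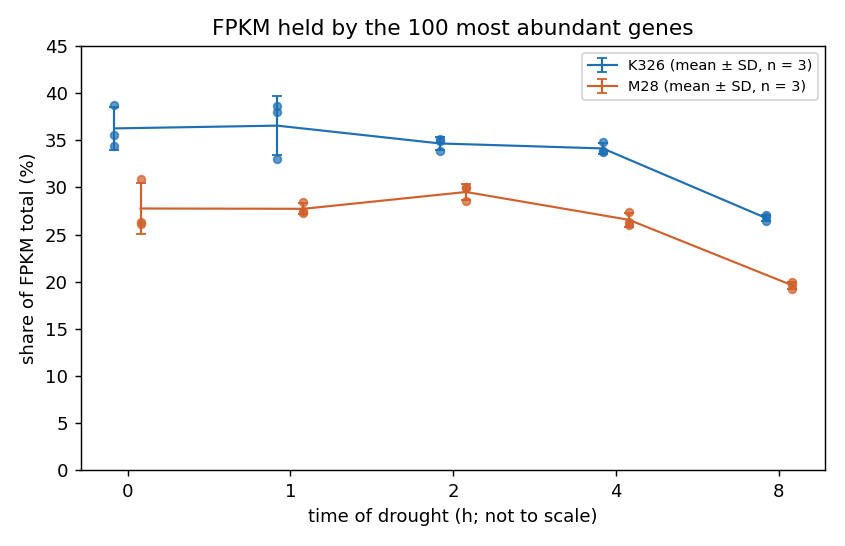
Share of the FPKM total in percent held by the 100 most abundant genes, by time in hours, with points for libraries and lines and bars for the mean and SD of 3 libraries. The share is lower in M28 than in K326 at every time and is lowest at 8 h in both, at 26.77% in K326 and 19.64% in M28.

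The first comparison followed the K326 leaves from 0 h. The gene Nitab4.5_0000723g0160 rose from 0.494 ± 0.273 FPKM (SD, n = 3) at 0 h to 446 ± 103 FPKM at 8 h, a log2 fold change of 8.21 (SE 0.371, adjusted p = 3.03e-15). The gene Nitab4.5_0000175g0140 stayed near its starting level at 1 h, reached 149 ± 13.3 FPKM at 4 h and 315 ± 25.4 FPKM at 8 h (log2 fold change 8.01, SE 0.151, adjusted p = 1.24e-24). Among the most abundant transcripts, Nitab4.5_0000495g0040 fell from 4184 ± 397 to 39.5 ± 8.05 FPKM at 8 h, by way of 2052 ± 140 FPKM at 4 h (log2 fold change -6.71, SE 0.246, adjusted p = 8.8e-18). Nitab4.5_0000982g0170 took a similar course, from 2564 ± 329 to 19.0 ± 5.92 FPKM (log2 fold change -7.04, SE 0.206, adjusted p = 6.72e-20). Gene names and descriptions could not be matched to these IDs.

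In K326, 13654 of 19599 genes changed over the course, and 3551 of them reached a 2-fold change at some time, 2205 upward and 1346 downward at their largest change. The number changed against 0 h was 6028 at 1 h, 6762 at 2 h, 8319 at 4 h and 11396 at 8 h. The count at 1 h was 3175 when only the groups compared were fitted. Genes changed at least 2-fold rose in number from 974 at 1 h to 2850 at 8 h, of which 1777 were higher and 1073 lower. Of 3549 genes with a 2-fold change that passed its own test, 66.2% had their largest change at 8 h and 12.7% at 1 h. The split between directions depended on scaling. Of the genes called at 2, 4 and 8 h, 69.8, 65.2 and 71.3% were higher, against 48.7, 48.5 and 50.1% after median-of-ratios scaling and 52.8, 49.9 and 51.2% after quantile normalization. Both of these centre the genes by construction, and rescaling to equal totals gave 72.4, 67.2 and 76.5%. At 8 h the median log2 change of all genes was 0.21 with the deposited values and 0.01 after median-of-ratios scaling.

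The same course was followed in M28. The gene Nitab4.5_0005259g0040 rose to 373 ± 17.5 FPKM at 4 h and stood at 74.3 ± 7.46 FPKM at 8 h (log2 fold change at 4 h 8.17, SE 0.188, adjusted p = 4.21e-21). Its values at 0 h were 0.282 and 0.704 FPKM in replicates 3 and 2, and it was listed at 0 in replicate 1. Nitab4.5_0000175g0140 rose in M28 as well, to 235 ± 22.6 FPKM at 8 h (log2 fold change 7.59, SE 0.151, adjusted p = 3.09e-24). The abundant genes Nitab4.5_0000495g0040 and Nitab4.5_0000982g0170 fell to 32.8 ± 18.1 and 12.1 ± 2.92 FPKM at 8 h, with log2 fold changes of -6.61 (SE 0.246, adjusted p = 3.27e-18) and -6.47 (SE 0.206, adjusted p = 1.36e-19).

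In M28, 11737 genes changed over the course, and 3032 of them reached a 2-fold change, 1736 upward and 1296 downward. The number changed against 0 h was 4548 at 1 h, 4717 at 2 h, 6840 at 4 h and 10198 at 8 h. Of 3026 genes with a 2-fold change that passed its own test, 70% had their largest change at 8 h and 7.7% at 1 h. Of the genes called at 1, 2 and 4 h, 54.4, 47.7 and 56.9% were higher. At 8 h, 63.7% of the genes called were higher, against 48.8% after median-of-ratios scaling and 50.6% after quantile normalization. After rescaling to equal totals it was 68.5%. One of the 8 h libraries, replicate 3, had a relative depth of 0.488, and without it 9399 genes were called at 8 h.

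**Figure D3:**
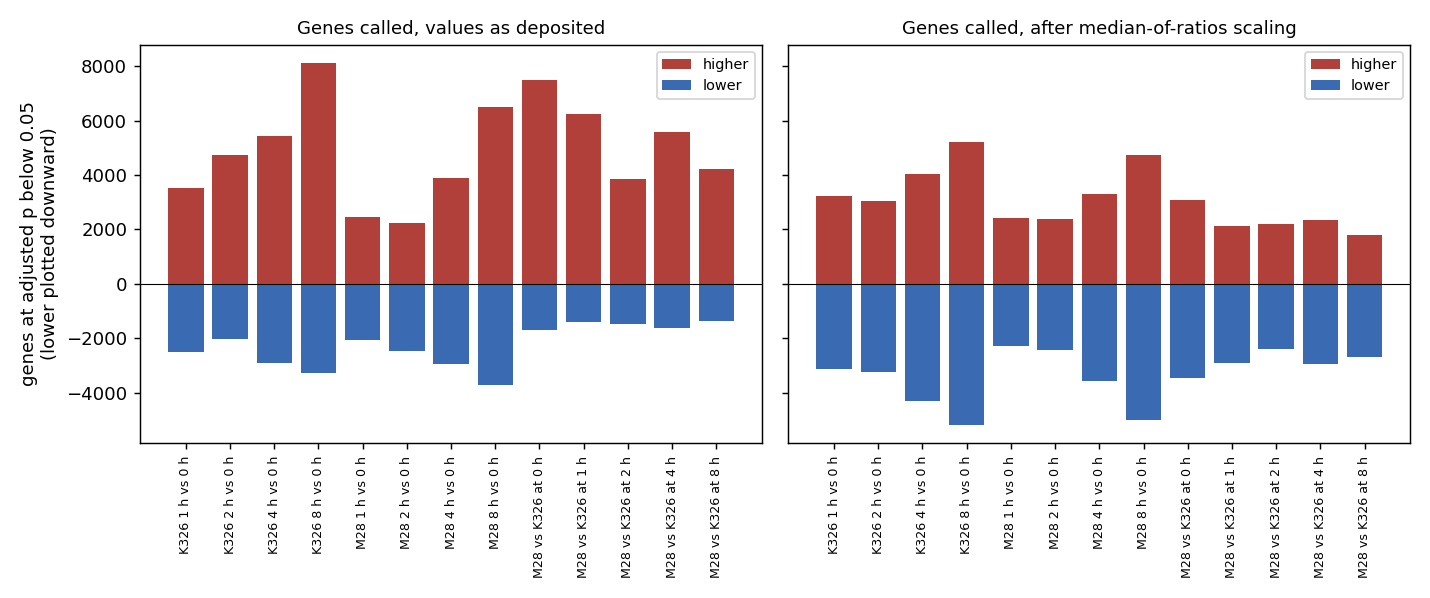
Number of genes at an adjusted p below 0.05 that were higher (upward) or lower (downward) in each comparison, from the deposited values on the left and after median-of-ratios scaling on the right. With the deposited values 81.5% of the genes called between genotypes at 0 h were higher in M28, and after the scaling 47.3% were. That scaling sets the median gene to 0 by construction.

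The responses of the genotypes were then compared gene by gene, each against its own 0 h libraries, so that the fold changes shared no library. The calls in both genotypes used the same residual spread of each gene, so the lists were not fully independent. At 8 h, 5516 genes rose in both genotypes, where independent lists of these sizes would share 2695, and 2419 fell in both, where independent lists would share 617.2. Only 82 genes rose in K326 and fell in M28 and 34 did the opposite. These counts are from the deposited values. After median-of-ratios scaling 5213 genes in K326 and 4755 in M28 were higher at 8 h, and 5191 and 4988 were lower. The split within each genotype thus depended on the scaling, and the shared genes were not recounted under it. The correlation of the responses at 8 h was 0.884 under it. Dividing a library by a single factor shifts nearly all its log2 values alike, so this scaling could hardly move a correlation. Across genes, which are not independent replicates, the log2 fold changes of K326 and M28 had a Pearson correlation of 0.727 at 1 h (jackknife SE over libraries 0.0631), 0.704 at 2 h (0.0306), 0.836 at 4 h (0.0154) and 0.884 at 8 h (0.0196). Among genes changed at least 2-fold in K326, the median ratio of the M28 to the K326 log2 change was 0.657 at 1 h and 0.829 at 8 h. Among genes changed at least 2-fold in M28, the median ratio of the K326 to the M28 change was 0.886 at 1 h and 0.963 at 8 h. Each list was chosen on its own genotype, which lowers both ratios.

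The mutant was compared with its parent at 0 h, before drought. The gene Nitab4.5_0001476g0060 stood at 219 ± 37.4 FPKM (SD, n = 3) in M28 and 3.65 ± 2.78 FPKM in K326 (log2 difference 5.71, SE 0.274, adjusted p = 3.08e-14). Nitab4.5_0000028g0320 stood at 149 ± 58.7 FPKM in M28 and 1.94 ± 0.229 FPKM in K326 (log2 difference 5.60, SE 0.408, adjusted p = 8.06e-11). In the other direction, Nitab4.5_0003766g0010 stood at 99.3 ± 27.8 FPKM in K326 and 2.58 ± 2.53 FPKM in M28 (log2 difference -4.998, SE 0.539, adjusted p = 6e-08). Nitab4.5_0005041g0010 had 22.0 ± 3.69 FPKM in K326 at 0 h and was listed at 0 in all 15 M28 libraries (adjusted p = 1.1e-19).

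At 0 h, 9212 genes differed between the genotypes, 7504 higher and 1708 lower in M28, and 1070 differed at least 2-fold, 747 higher and 323 lower. The share higher was 81.5% with the deposited values, 47.3% after median-of-ratios scaling and 54.6% after quantile normalization. Both scalings centre the median gene or equalize the distributions by construction, so they cannot decide the direction. Rescaling to equal totals, which does neither, gave 88%. It fixes the sum instead. The 100 most abundant genes held 27.76% of the total in M28 and 36.25% in K326 at 0 h. Equal totals must then raise the sum of the other genes in M28, so this rescaling cannot decide the direction either. The median log2 difference of all genes was 0.22 with the deposited values and was 0.00 after median-of-ratios scaling. The direction of small differences thus depended on the scaling. The genes named above kept their direction under each scaling tried, but they were picked for the largest differences, which shifts of this size could not reverse.

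The difference between genotypes was then averaged over the 5 times. Nitab4.5_0001476g0060 was higher in M28 throughout (log2 difference 5.86, SE 0.123, adjusted p = 6.19e-23), with group means between 155 and 270 FPKM in M28 and between 1.60 and 3.65 FPKM in K326. Nitab4.5_0000028g0320 was likewise higher (log2 difference 4.75, SE 0.183, adjusted p = 3.47e-17). Nitab4.5_0001107g0060 was lower in M28 (log2 difference -3.91, SE 0.052, adjusted p = 1.73e-27), with group means between 16.7 and 26.5 FPKM in K326 and between 0.351 and 0.699 FPKM in M28. Nitab4.5_0005041g0010 had group means between 22.0 and 29.1 FPKM in K326 and was listed at 0 in M28 (adjusted p = 7.56e-29).

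Over all times, 13354 genes differed, 10615 of them (79.5%) higher in M28, against 48.1% after median-of-ratios scaling and 53.3% after quantile normalization. At least 2-fold differences were found for 396 genes higher and 204 genes lower in M28. The number that differed at single times was 7653 at 1 h, 5336 at 2 h, 7172 at 4 h and 5581 at 8 h, with 81.8, 72.2, 77.6 and 75.5% higher in M28. Those shares were 42.3, 47.8, 44.6 and 40.3% after median-of-ratios scaling and 50.2, 54.2, 53.7 and 52.3% after quantile normalization, which both centre the genes by construction. After rescaling to equal totals they were 88.2, 83.3, 86.5 and 85.2%. At 1 h the count was 5002 and 4839 under median-of-ratios scaling and quantile normalization, and 4361 when only the groups compared were fitted. The differences at 0 h and at 8 h, which share no library, had a Pearson correlation of 0.66 across genes, and 3120 genes were higher and 736 lower in M28 at both times, where independent lists would share 1614 and 119. These counts are from the deposited values. After median-of-ratios scaling 1803 genes in all were higher and 2673 lower in M28 at 8 h, so the split at 8 h depended on the scaling. The genes shared by both times were not recounted under it.

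**Figure D4:**
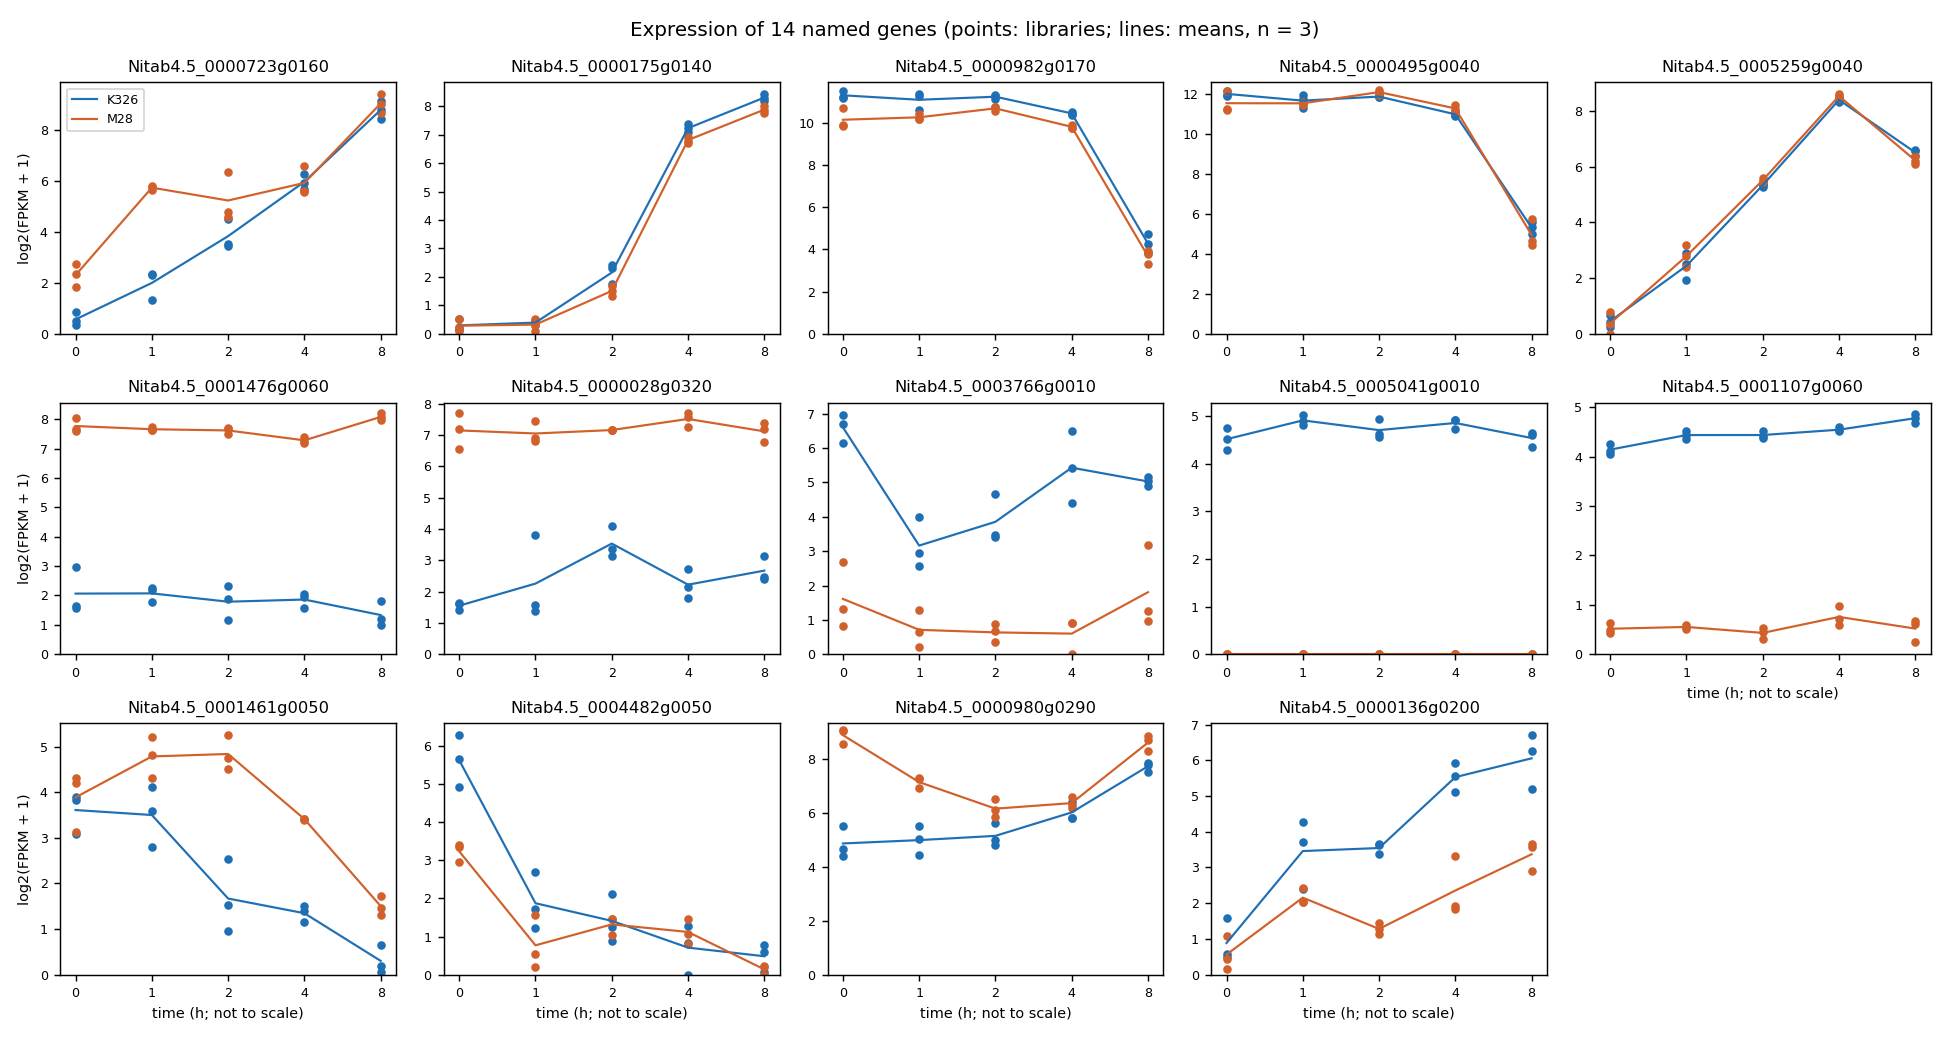
Expression as log2(FPKM + 1) of the 14 genes named by the rule against time in hours, with points for libraries and lines for the means of 3 libraries per genotype and time. Nitab4.5_0000495g0040 and Nitab4.5_0000982g0170 drop between 4 and 8 h in both genotypes, and Nitab4.5_0001476g0060 lies between 146 and 293 FPKM in the M28 libraries and at no more than 6.86 FPKM in the K326 libraries.

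Whether the time course itself differed between the genotypes was tested with the interaction. Nitab4.5_0000980g0290 fell in M28 from 480 ± 93.6 FPKM at 0 h to 82.2 ± 13.1 FPKM at 4 h, while in K326 it went from 29.95 ± 13.4 to 65.2 ± 16.7 FPKM (difference of the log2 changes at 4 h -3.68, SE 0.382, adjusted p = 6.76e-06). The fall in M28 did not last: at 8 h this gene stood at 394.8 ± 73.4 FPKM in M28 and 212.8 ± 24.8 FPKM in K326. Nitab4.5_0001461g0050 stood at 2.53 ± 2.00 FPKM in K326 at 2 h, from 11.6 ± 3.56 at 0 h, and at 28.3 ± 7.96 FPKM in M28, from 14.7 ± 6.08 (difference 2.89, SE 0.497, adjusted p = 0.0044). Nitab4.5_0000136g0200 reached 46.5 ± 13.4 FPKM in K326 and 4.77 ± 3.63 FPKM in M28 at 4 h, from 0.972 ± 0.913 and 0.534 ± 0.535 FPKM at 0 h (difference -2.85, SE 0.596, adjusted p = 0.0119). Nitab4.5_0004482g0050 went from 52.2 ± 23.9 FPKM to values between 0 and 1.44 FPKM at 4 h in K326, and from 8.51 ± 1.51 to 1.21 ± 0.512 FPKM in M28 (difference 2.80, SE 0.555, adjusted p = 0.00976). With a pseudocount of 0.1 FPKM these last differences, for Nitab4.5_0000136g0200 and Nitab4.5_0004482g0050, had adjusted p values of 0.114 and 0.119.

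The interaction was called for 1995 genes, and 436 of them reached a 2-fold difference of the responses. By time it was called for 525 genes at 1 h, 1090 at 2 h, 795 at 4 h and 1792 at 8 h. Of the 1792 genes at 8 h, 429 rose and 145 fell in K326 and were not called in M28, 103 rose and 237 fell in M28 and were not called in K326, 116 were called in opposite directions, and 762 changed in the same direction in both, 556 of these by more in K326. The share with a higher response in M28 was 36, 22, 21.6 and 25.4% at 1, 2, 4 and 8 h with the deposited values, 50.3, 60.5, 47.2 and 49.3% after median-of-ratios scaling and 39.6, 50.1, 42 and 44.7% after quantile normalization. After rescaling to equal totals it was 30, 18.8, 21.6 and 21.6%. The count at 1 h was 78 when only the groups compared were fitted, and single libraries moved the counts per time by over 1.5 times. At 1 h the count was 344 and 247 without M28 0 h replicates 2 and 3, 348 and 217 without M28 1 h replicates 1 and 3, 279 without K326 0 h replicate 2, and 849 and 285 without K326 1 h replicates 2 and 3. It was 719 and 646 at 2 h without M28 0 h replicates 2 and 3, 468 and 495 at 4 h without M28 0 h replicate 3 and K326 4 h replicate 1, and 1180 at 8 h without M28 0 h replicate 3.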

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

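The tests that divide each library by its total outside the 100 most abundant genes were chosen after the results were seen. The result singled out here is that the time courses of the genotypes differed, by a test of the difference itself, for 1995 genes. Of these, 1465 (73.4%) were called again after median-of-ratios scaling and 1407 (70.5%) after quantile normalization. Without M28 0 h replicate 3, 1326 (66.5%) were called again, the fewest with any library left out. The named genes with the largest differences of the log2 response, M28 minus K326, were Nitab4.5_0001461g0050 at 2 h (2.89), Nitab4.5_0004482g0050 at 4 h (2.80), Nitab4.5_0000980g0290 at 4 h (-3.68) and Nitab4.5_0000136g0200 at 4 h (-2.85). With a pseudocount of 0.1 FPKM, Nitab4.5_0004482g0050 and Nitab4.5_0000136g0200 were no longer called (adjusted p = 0.119 and 0.114). Of 100 groupings in which the genotype labels were exchanged within times after the average genotype difference had been taken out, the real one included, 1 gave as many genes, and the highest of the others gave 116. Chance in how the libraries were grouped is therefore an unlikely source of this many calls, with 1 of 100 the smallest share these groupings can give. Mixed groupings carry real differences into the residual spread, which lowers their counts. The test thus bears on whether responses differed and not on the exact number of genes.

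The direction of these differences is a separate question. At 2 h, 850 of 1090 genes had a lower response in M28, and at 0 h 81.5% of the genes that differed were higher in M28. After median-of-ratios scaling 39.5% of the genes called at 2 h were lower and 47.3% of those called at 0 h were higher, but that scaling sets the median gene to 0 by construction, so these values do not decide whether a few abundant genes caused the excess. With each library divided by its total outside the 100 most abundant genes, 74.4% of the genes called at 0 h were still higher in M28 (72.2 to 75.2% with each of 6 libraries left out) and 68.3% of those called at 2 h were still lower in M28 (65 to 70.1% with each of 12 libraries left out), which argues against these 100 genes alone as the cause. A difference in depth acting on low genes is also argued against, since 75.3% were higher in M28 at 0 h among genes with a mean of at least 20 FPKM and the relative depth at 0 h was 0.983 in M28 and 0.987 in K326. With the 1000 most abundant genes left out of the totals, 62.2% of the genes called at 0 h were higher in M28. At 2 h, 352 of the 847 genes called (41.6%) had a higher response in M28, against 31.7% with the 100 genes left out. The excess was thus smaller at both times with that division, and the split at 2 h was closer to even. A wider shift in composition or a difference in RNA content between the genotypes, which no spike-in measures here, stays open.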

How the results depend on the processing

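The alternatives for genes with an isolated 0, for the correlations and for the share of the abundant genes were chosen after seeing the data. Of 208 counts under other settings, 203 lay within 1.5 times the reported count, as did 204 of 216 counts with a library left out. The exceptions among settings were M28 against K326 at 1 h, with 5002 genes under median-of-ratios scaling, 4839 under quantile normalization and 4361 when only the groups compared were fitted, and under that last setting also K326 at 1 h with 3175 genes and the interaction at 1 h with 78. Fewer libraries stood behind the spread under that setting, but at 2 h as well as at 1 h. At 2 h it gave 6120 genes against 5336 between genotypes and 1267 against 1090 in the interaction. In K326 at 2 h it gave 5730 against 6762. Fewer libraries alone thus do not account for the larger falls at 1 h. The cause of these changes was not tested. A count leaves open which genes were called. After median-of-ratios scaling 4796 of the 9212 genes called between genotypes at 0 h (52.1%), 3507 of 7653 at 1 h (45.8%) and 583 of the 1090 in the interaction at 2 h (53.5%) were called again. With a library left out, the interaction was called for 217 to 849 genes at 1 h, 646 to 1480 at 2 h, 468 to 845 at 4 h and 1180 to 1952 at 8 h, and over all times for 1354 to 2357. The libraries that moved these counts by over 1.5 times are named in the report. The correlation between the genotypes' responses at 2, 4 and 8 h was 0.660, 0.806 and 0.861 with a pseudocount of 0.1 FPKM and 0.757, 0.869 and 0.909 among genes with a mean of at least 5 FPKM. With no filter it was 0.671 at 2 h and 0.815 at 4 h. With a library left out it ranged from 0.673 to 0.705 at 2 h, the lowest without M28 0 h replicate 1, and from 0.818 to 0.835 at 4 h, the lowest without K326 0 h replicate 1. For the named genes, 189 of 191 values under other settings and 384 of 384 with a library left out kept their direction and call. These genes were picked for large changes without overlap between the libraries, which by itself favours such an outcome. The exceptions, with a pseudocount of 0.1 FPKM, were Nitab4.5_0004482g0050 (3.79, adjusted p = 0.119) and Nitab4.5_0000136g0200 (-2.67, adjusted p = 0.114), and 0 reversed.

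The replicate numbers did not pair the libraries: same-numbered libraries had a mean correlation of 0.0103 in their deviations from the group means (-0.298 to 0.207), 17 of 135 pairs were over 0.1, and 12 of 30 libraries were closest to their own number. With the replicate number as a block the interaction was called for 1817 genes, the K326 course for 13509, the M28 course for 11613 and the genotype difference for 13318, and no count moved by over 1.5 times. Depth limits the low genes most in M28 8 h replicate 3. Without it 4767 genes differed between genotypes at 8 h and 2023 in the interaction.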

Other observations

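The counts of early and constant genes below, the tests on components of the libraries later than 0 h and the reading of the detrended correlation were chosen after the data were seen. The genes that changed at least 2-fold at 1 h were followed to 8 h. They were chosen on their value at 1 h, which by itself makes the later value smaller, 8 h was not tested against 1 h, and a missing call does not show a return to the 0 h level. Of 518 genes that rose at least 2-fold in K326 at 1 h, 281 were still at least 2-fold higher at 8 h, 108 were not called at 8 h and 46 were lower than at 0 h. In M28, 378 genes rose at least 2-fold at 1 h, of which 211 were still at least 2-fold higher at 8 h, 83 were not called and 24 were lower. Of the genes that fell at least 2-fold at 1 h, 265 of 456 in K326 and 195 of 284 in M28 were still at least 2-fold lower at 8 h. Both times were compared with the same 0 h libraries, and unchanged groups simulated against shared libraries had a correlation of 0.502 and a covariance of 0.0165, where the observed 1 h and 8 h responses had 0.503 and 0.204 in K326 and 0.519 and 0.171 in M28.

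Other genes differed between the genotypes at every time. The differences at the 5 times share no library, but their calls used the same residual spread of each gene. In these comparisons 1681 genes were called higher in M28 at all 5 times, 150 of them at least 2-fold each time. Another 430 were called lower, 70 of them at least 2-fold each time. That split depended on the scaling: after median-of-ratios scaling 594 genes were higher and 890 lower at all 5 times, 101 and 100 of them at least 2-fold each time. At the extreme, 3 genes were listed at 0 in all 15 M28 libraries and at 1 FPKM or more in all K326 libraries: Nitab4.5_0005041g0010 (18.4 to 31.6 FPKM in K326), Nitab4.5_0000202g0480 (3.93 to 7.26) and Nitab4.5_0000673g0190 (1.48 to 3.74). Another 3 were listed at 0 in all K326 libraries: Nitab4.5_0000305g0130 (1.88 to 13.96 FPKM in M28), Nitab4.5_0003364g0010 (6.76 to 10.5) and Nitab4.5_0000002g0110 (2.58 to 4.83). These 6 were picked after their values were seen.

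The M28 libraries had higher scores than the K326 libraries on the first principal component at every time, by 30.6% of the K326 distance from 1 to 8 h at 0 h, 27.9% at 1 h and 14.7 to 16.8% later. On the first component of the 24 libraries later than 0 h the offset was 8.68% at 0 h and 12% at 1 h, without overlap between the genotypes, and -2.34 to 3.01% at 2, 4 and 8 h, where the libraries overlapped, and on that of the 12 K326 libraries later than 0 h it was 8.24% at 0 h, 14% at 1 h and 0.989% at 2 h, and -4.94% at 4 h and -4.27% at 8 h, without overlap at 0, 1, 4 and 8 h. The genotype difference at 0 h had a correlation across genes of 0.0545 with the K326 change from 1 to 8 h, which shares no library with it. K326 scored -41.14 at 0 h and -42.03 at 1 h on the component of the 24 libraries, and -40.33 and -43.08 on that of the 12. On the component of all libraries it scored -59.59 and -34.59. The reduced components and the correlation thus leave out most of the K326 change from 0 to 1 h. These tests cannot tell whether M28 at 0 h lies toward that change. The use of the same K326 0 h libraries and a genotype difference taken up by the component stay open as explanations. These tests do not separate them or account for the offsets that were left. A uniform shift (correlation 0.123 among genes with a mean of at least 20 FPKM, between the bounds set) and a trend with expression level (0.0393 after its removal, from a value already below 0.1) stay open.

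A further hypothesis was that differences between the genotypes lie in linked blocks, as variants from mutagenesis or an outcross could leave. Of 11499 pairs of adjacent IDs on one scaffold, 20 held genes that both differed at least 2-fold the same way over all times, 3.37 times the mean of 10000 shuffles (95% Poisson interval 2.06 to 5.21, permutation p = 1e-04, the smallest these shuffles can give). For the same number of genes most changed in K326 at 8 h, 31 pairs gave a ratio of 5.61 (3.81 to 7.96, permutation p = 1e-04). The prediction for linked blocks was a larger ratio for the genotype difference, and the ratio was smaller, so the prediction was not met. The genotype ratio was 0.602 times the other (95% exact Poisson interval 0.325 to 1.09), so a slightly larger ratio is not excluded. This interval was chosen after the values were seen, and by the prediction alone the smaller ratio would have counted against linked blocks. Neighbouring genes also changed together in K326 between 0 and 8 h, within 1 genotype. That set is therefore no baseline free of such pairs, the comparison cannot decide, and linked blocks stay open.

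Other groupings of the libraries were counted for each test. For the K326 course, 1 of 100 groupings, the real one with 13654 genes, gave as many, and the highest other gave 8465. For the M28 course it was 1 of 100, with 11737 genes against 6926, and for the genotype difference over all times 1 of 100, with 13354 against 5627. Chance in the grouping is an unlikely source of this many calls, with 1 of 100 the smallest share these groupings can give. The exact counts are not tested by this. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 6028 and 693 genes in K326 at 1 h, 6762 and 1 at 2 h, 8319 and 0 at 4 h, and 11396 and 0 at 8 h. In M28 they gave 4548 and 0 at 1 h, 4717 and 0 at 2 h, 6840 and 0 at 4 h, and 10198 and 1 at 8 h. Between genotypes they gave 9212 and 1 at 0 h, 7653 and 197 at 1 h, 5336 and 0 at 2 h, 7172 and 1 at 4 h, and 5581 and 1 at 8 h.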
